A study of Caenorhabditis elegans with 24 samples.

How the data were processed

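The deposited values are on the log2 scale and were made by the authors with RMA, per the submitters' processing notes. RMA is a method of background correction, quantile normalization and summary of the probes of each probe set. The version and settings of RMA were not given in the sources used here. The arrays were whole-transcript gene arrays for C. elegans made by Affymetrix (Gene 1.1 ST). The 12 adult arrays share a distribution that differs from that of the 12 larval arrays, and 3 probe sets are blank in every adult array, so the stages look to have been normalized in separate runs. For that reason adults and larvae were not tested against each other, and the comparison of stages in the wild type that had been planned was left out. The difference between stages in the response to temperature was tested, as a difference of differences within each stage.

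Of 29317 probe sets, 25484 had exactly 1 gene symbol, 700 had several and 3133 were not named in the platform table. For 25433 of the probe sets with 1 symbol the gene identifier was found in the RefSeq table, with 0 symbols that differed. For 41 genes with more than 1 probe set the one with the highest mean was kept, which left out 47. After the 3 blank probe sets, 25434 genes were tested and no filter on dim genes was applied. The 3833 probe sets without a single gene were tested separately.

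R 4.3.3 and limma 3.58.1 were used. Group means of the 8 groups were fitted over all 24 arrays with limma (lmFit, contrasts.fit and eBayes), with 16 residual and 6.06 prior degrees of freedom. All p-values of genes come from limma's moderated test, two-sided, adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. There were 11 comparisons: 4 of temperature, 4 of genotype, temperature by genotype in each stage, and temperature by stage in the wild type. Genotype differences are daf-16 minus wild type, temperature by genotype is the mutant effect minus the wild-type effect, and temperature by stage is the adult effect minus the larval effect. The 24 gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 24 lists, and again with a correlation estimated for each list. The class 1 list shares 4 genes with the heat shock list, 4 with the antimicrobial list and 3 each with the detoxification and antioxidant lists, and the antimicrobial and neuropeptide lists share 11. The class 2 list shares 2 genes with the vitellogenins and 2 with the antimicrobial list.

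The comparisons, the gene lists, the alternatives, apart from the one without preparation 3 of larvae at 25 °C, and the rule for named genes were chosen before the data were examined. The rule names daf-16 and the sentinel genes vit-2, sod-3, mtl-1, hsp-16.2, fat-7, trpa-1, gcy-8 and msp-142, the last of which had no probe set of its own. It also names the 10 largest rises and falls with temperature in wild-type adults and in wild-type larvae, and the 5 largest in each direction elsewhere. These were taken among genes with an adjusted p under 0.05, a name of letters and a number, and groups of 3 arrays that do not overlap. It adds up to 4 members of each list with an adjusted p under 0.05, by size. Of the sentinels, sod-3, hsp-16.2, vit-2, trpa-1 and gcy-8 were called in none of the 11 comparisons. Group means of hsp-16.2 (1.18 to 1.75), sod-3 (2.25 to 3.46) and gcy-8 (1.51 to 3.06) lay below the array medians of their stage. For these genes the lack of calls says little.

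Whether the preparation numbers in the titles pair the arrays was checked by correlating, across genes, the deviations from the group means of arrays with the same number. All 3 numbers were above the limit of 0.1 for temperature in wild-type adults (0.26 to 0.34) and genotype in larvae at 25 °C (0.15 to 0.45), and not in the other 6 comparisons of 2 groups. The number was therefore not used in the fit reported, and a fit with it as a block is given as an alternative. The labels do not say whether the 3 preparations of a group were separate cultures, so the p-values measure only the spread between preparations. The median SE of a gene was 0.16 for a comparison of 2 groups and 0.22 for a difference of differences, and the median SD within a group was 0.18 in adults and 0.195 in larvae.

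The calculations were tested on simulated data with 25434 genes and changes of known size. Of changes of 1 log2 unit, 85.1% were recovered for temperature in wild-type adults, 88.1% in wild-type larvae, 43.3% for temperature by genotype in adults, 52.2% in larvae and 57.5% for temperature by stage. Of changes of 0.5 log2 units, 32.8%, 17.9%, 4.48%, 0% and 8.21% were recovered. Of the calls, 5.23%, 6.16%, 2.04%, 4.76% and 3.96% were false. The 1 list that was shifted was called, and 0 others. The simulated genes varied independently, and 153 were called for temperature in wild-type adults, where the data gave 7667. The recovery in the data can therefore differ. The list check could not show false calls from correlated genes, whose estimated correlation reached 0.87 in the vitellogenins.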

Results

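Messenger RNA was measured in the nematode Caenorhabditis elegans on 24 Affymetrix gene arrays, 1 for each RNA preparation. The preparations form 8 groups of 3, from wild-type worms and daf-16 mutants, at 2 stages and at 15 °C or 25 °C. Adults were kept at the temperature for 3 days after the late L4 stage, the last larval stage, and about 120 were pooled per preparation. Larvae grew at the temperature from the embryo and about 300 were pooled as late L4. Adults were thus matched by days and larvae by stage. The adult comparisons cannot separate temperature itself from how far adult life had advanced. The gene daf-16 encodes the FOXO transcription factor at the end of the insulin-like signalling pathway, which limits lifespan in this worm. The groups allow the response to temperature in larval life to be set against that in adulthood, and the part of each that needs daf-16 to be measured. The array medians lay between 3.55 and 3.70 on the log2 scale in adults and between 2.96 and 3.08 in larvae. Arrays of 1 group correlated across genes at 0.991 to 0.996 in adults and 0.989 to 0.994 in larvae, genes not being independent replicates. Differences below are in log2 units with the SE of the fit, each between groups of 3 arrays, and a rise or fall with temperature is 25 °C over 15 °C. Genes given as largest, highest or lowest are so among called genes that have a name of letters and a number and groups of 3 arrays that do not overlap, and genes known only by a sequence name can exceed them.

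The targeted gene was lower in every mutant group. In adults, daf-16 stood at 10.46 ± 0.09 (SD, n = 3) in the wild type and 8.43 ± 0.36 (SD, n = 3) in the mutant at 15 °C, and at 10.59 ± 0.03 (SD, n = 3) and 8.58 ± 0.34 (SD, n = 3) at 25 °C. In larvae the values were 8.59 ± 0.09 (SD, n = 3) and 6.45 ± 0.10 (SD, n = 3) at 15 °C, and 8.68 ± 0.10 (SD, n = 3) and 6.19 ± 0.20 (SD, n = 3) at 25 °C. By limma the mutant was lower by -2.04, -2.01, -2.14 and -2.48, with adjusted p = 1.2e-07, 5.3e-08, 7e-08 and 6.9e-09. Where the probes lie relative to the deleted part of the gene is not known, so the remaining signal is not read as transcript.

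**Figure D1:**
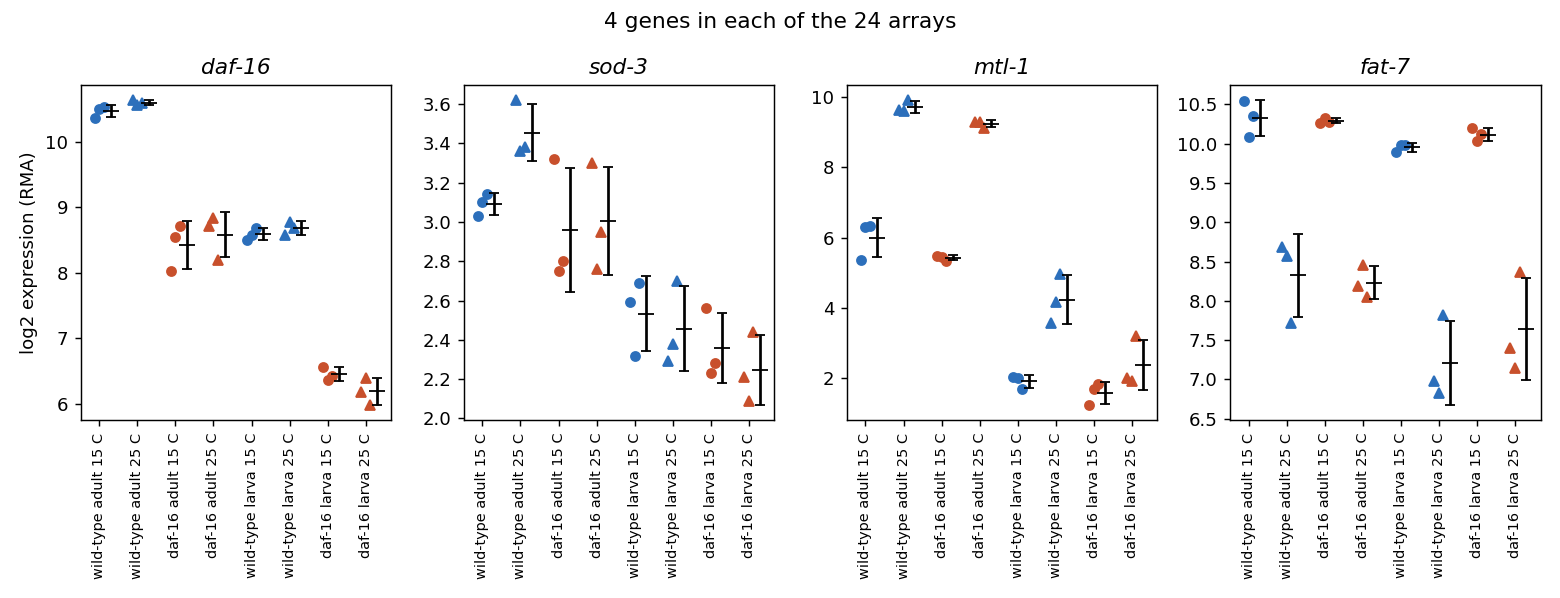
Each array's log2 value of daf-16, sod-3, mtl-1 and fat-7 in the 8 groups, with the mean and SD of each group of 3; wild type in blue, daf-16 mutants in red, circles at 15 °C and triangles at 25 °C. Adults and larvae appear to have been normalized separately, so levels are compared within a stage; mtl-1 rose from 6 to 9.71 in wild-type adults and fat-7 fell from 10.32 to 8.32.

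In wild-type adults the largest rises among genes with a name of letters and a number were msp-78, a major sperm protein, by 5.12 ± 0.60 (SE), dbd-13 by 4.41 ± 0.25, abf-2, an antimicrobial peptide, by 4.36 ± 0.22, and lys-7, a lysozyme, by 3.90 ± 0.24. Next came pqn-73 (3.88), icmt-1 (3.87), tts-2 (3.76), dct-8 (3.73), the metallothionein mtl-1 (3.71) and the T-box gene tbx-43 (3.67). The largest falls were spp-9, a saposin-like protein, at -3 ± 0.40, followed by the C-type lectins clec-10, clec-53 (-2.22), clec-52 (-2.18) and clec-3. The protease cpr-8 (-2.14), ugt-62 (-2.12), spd-3 (-2.1), fat-7 (-2), which makes oleic acid from stearic acid, and rips-1 (-1.99) completed the 10. msp-78 varied widely between the warm arrays (7.27 ± 2.01, SD, n = 3), and msp and nspd genes have near-identical copies, so single members are uncertain. By limma, adjusted p was 1e-06 for msp-78 and at most 5.5e-06 for the other 19 genes. In all, 3851 of 25434 genes rose and 3816 fell, of which 1524 and 271 moved at least 2-fold. With each array centred on its median, 3401 rose and 6059 fell, so the share that rose moved from 50.2% to 36%.

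Among the lists fixed beforehand, genes that DAF-16 raises (class 1) mostly rose in wild-type adults: 20 of 30 rose and 1 fell (adjusted over the list alone, 21 and 2), led by lys-7, mtl-1 and dod-6 (2.50 ± 0.22). Of 71 moulting genes, 42 rose and 0 fell (adjusted over the list alone, 43 and 1), among them lpr-3 (3.04), the hedgehog-related wrt-10 (2.94) and noah-1 (2.90), a component of the larval body cover. Both lists kept their calls with an estimated correlation, with camera adjusted p = 3.1e-09 and 3.3e-15 at the preset correlation and 0.00017 and 0.042 with an estimated correlation. Neuropeptide and insulin-like genes rose in 76 of 152 cases and fell in 6 (adjusted over the list alone, 79 and 8), with ins-7, an insulin-like peptide, at 3.31 ± 0.23, nlp-34 at 3.28 and nlp-49 at 2.86. Pan-neuronal genes rose in 15 of 24 cases and fell in 0 (adjusted over the list alone, 15 and 2), including sbt-1 (1.74) and ida-1 (1.58), which act in dense-core vesicles. Body wall muscle genes rose in 17 of 27 cases and fell in 2 (adjusted over the list alone, 18 and 2), led by the myosin heavy chain myo-3 (1.68 ± 0.25). For these 3 lists the adjusted p was 2.6e-14, 1.2e-06 and 9.6e-06, and adjusted p = 0.085, 0.085 and 0.24 with an estimated correlation. Sperm genes rose in 10 of 36 cases and fell in 0 (adjusted over the list alone, 12 and 0; adjusted p = 0.00027), with msp-78, nspd-7 (3.43) and nspd-1 (3.26) the largest. Early embryo genes rose in 25 of 61 cases and fell in 2 (adjusted over the list alone, 25 and 3; adjusted p = 9e-04), led by sdz-28 (2.01). Thermosensation and TRPA-1 pathway genes rose in 8 of 23 cases and fell in 2 (the same counts adjusted over the list alone; adjusted p = 0.0082), led by ttx-1 (1.67), a homeobox gene of the thermosensory neurons, and the kinase cmk-1 (1.53). With an estimated correlation these 3 lists had adjusted p = 0.26, 0.26 and 0.24. In the comparisons below, lists called at the preset correlation and not described, some higher and some lower, all lost their calls with an estimated correlation.

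In wild-type adults 3 lists were called lower at the preset correlation only, with most of their genes not called. Of 39 DNA replication and cell cycle genes, 11 fell and 0 rose (the same adjusted over the list alone), led by zyg-1, a kinase of centriole duplication, at -0.82 ± 0.12. Proteasome genes fell in 11 of 33 cases and rose in 0 (adjusted over the list alone, 15 and 0), led by pas-5 (-1.08). Ribosomal protein genes fell in 14 of 74 cases and rose in 2 (adjusted over the list alone, the same), with rpl-11.2 the largest rise (0.86) and rpl-7A the largest fall (-0.81). Camera gave adjusted p = 0.0014, 0.00011 and 0.0077 for the 3 lists, and adjusted p = 0.46, 0.4 and 0.68 with an estimated correlation. After cyclic loess none of the 3 was called, at adjusted p = 0.19, 0.071 and 0.79. The remaining 13 lists were not called. Fatty acid desaturase and elongase genes rose in 9 of 24 cases and fell in 3 (adjusted over the list alone, 9 and 6; adjusted p = 0.11, but 0.029 after cyclic loess), with fat-7 the largest fall and fat-3 (1.19) the largest rise. Lipid breakdown genes split into 15 that rose, among them the lysosomal lipases lipl-2 (3.56) and lipl-1 (2.57), and 13 that fell of 43 (adjusted over the list alone, 16 and 14; adjusted p = 0.12, or 0.041 without wild-type adult 25 °C replicate 1). Heat shock protein genes rose in 5 of 21 cases, led by hsp-12.2 (1.24), and fell in 5 (the same over the list alone; adjusted p = 0.94). Endoplasmic reticulum stress genes rose in 3 of 20 and fell in 2 (the same adjusted over the list alone; adjusted p = 0.23, but 0.009 after cyclic loess). Genes that DAF-16 lowers (class 2) rose in 3 of 12 cases, led by ins-7, and fell in 2 (the same over the list alone; adjusted p = 0.21). Of 358 antimicrobial genes 80 rose and 42 fell (adjusted over the list alone, 80 and 44; adjusted p = 0.12, or 0.049 without wild-type adult 25 °C replicate 2 and 0.013 without the dimmest genes). Detoxification genes rose in 38 of 184 cases and fell in 25 (adjusted over the list alone, 38 and 26; adjusted p = 0.11, or 0.033 without wild-type adult 25 °C replicate 1), led by ugt-27 (2.36). Collagen genes rose in 28 of 171 cases, led by col-125 (3.64) and sqt-3 (3.37), and fell in 10 (adjusted over the list alone, 27 and 9; adjusted p = 0.21). Antioxidant genes rose in 6 of 29 and fell in 6 (adjusted over the list alone, 6 and 7; adjusted p = 0.99). Intestine genes rose in 8 of 31 and fell in 8 (the same over the list alone; adjusted p = 0.2), and oocyte and germ line genes rose in 3 of 36 and fell in 5 (the same over the list alone; adjusted p = 0.2). Oxidative phosphorylation genes rose in 2 of 41 and fell in 6 (adjusted over the list alone, 2 and 5; adjusted p = 0.2). Of 5 vitellogenin genes 0 rose and 1 fell, vit-1 at -0.78 (the same over the list alone; adjusted p = 0.89). By limma vit-1 had adjusted p = 0.015, but 0.066 after cyclic loess, and 0.051, 0.051 and 0.077 without wild-type adult 15 °C replicate 1, 25 °C replicate 1 and 25 °C replicate 2. Median, mean and test differed in sign for the heat shock list (-0.06, 0.07 and up), the collagens (-0.07, 0.12 and up), the antimicrobial list (-0.05, 0.12 and up), the antioxidants (-0.20, -0.04 and up) and the vitellogenins (0.02, -0.14 and down). sod-3, a mitochondrial superoxide dismutase and DAF-16 target, was at 0.36 with adjusted p = 0.1, and 0.035 with the preparation number as a block. Its mean was 3.09 at 15 °C and 3.46 at 25 °C, below the adult array medians.

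Without daf-16, adults still responded to temperature on a large scale. The largest rises in the mutant were mbug-1 (4.15 ± 0.27), nlp-34 (4.06), the lectins clec-71 (4.02) and clec-174 (3.99) and mtl-1 (3.81), and the largest falls were col-92 (-2.45 ± 0.32), spp-9 (-2.3), clec-10 (-2.13), fat-7 (-2.06) and acdh-2 (-2). By limma 3401 genes rose and 2857 fell, 1239 and 179 of them at least 2-fold, with adjusted p between 1.1e-09 and 0.00017 for those named. With each array centred on its median, the share that rose moved from 54.3% to 43.4% of 7108 genes. Moulting genes rose in 42 of 71 cases and fell in 0 (adjusted over the list alone, 44 and 1), led by wrt-10 (2.5). The call at adjusted p = 1.9e-16 had adjusted p = 0.054 with an estimated correlation. Neuropeptide genes rose in 63 of 152 cases and fell in 5 (adjusted over the list alone, 66 and 6; adjusted p = 7.5e-10). Pan-neuronal genes rose in 11 of 24 and fell in 0 (adjusted over the list alone, 12 and 0; adjusted p = 4.7e-06), with adjusted p = 0.16 and 0.11 with an estimated correlation. Class 1 genes rose in 10 of 30 cases and fell in 2 (adjusted over the list alone, 10 and 3; adjusted p = 0.0047). Class 2 genes rose in 6 of 12, led by ins-7 (2.34) and dod-24 (1.82), and fell in 2 (the same over the list alone; adjusted p = 0.0041), with adjusted p = 0.054 and 0.064 with an estimated correlation. Intestine genes rose in 11 of 31 cases and fell in 2 (the same over the list alone; adjusted p = 0.0047, adjusted p = 0.6 with an estimated correlation). Sperm genes rose in 7 of 36 and fell in 2 (the same over the list alone; adjusted p = 0.11), with msp-78 at 3.66. Muscle genes rose in 6 of 27 and fell in 2 (adjusted over the list alone, 8 and 2; adjusted p = 0.014), and thermosensation genes rose in 7 of 23 and fell in 0 (adjusted over the list alone, 7 and 1; adjusted p = 0.013). The muscle call was lost without mutant 15 °C replicate 1 (0.13) or 25 °C replicate 2 (0.059) and without the dimmest genes (0.11). Called lower were the proteasome list, with 6 of 33 down and 0 up (adjusted over the list alone, 4 and 0), the ribosomal list, with 16 of 74 down and 2 up (adjusted over the list alone, 15 and 2), and the DNA replication list, with 6 of 39 down and 0 up (adjusted over the list alone, 2 and 0). These 3 had adjusted p = 0.00026, 0.0037 and 0.017, and 0.019, 0.16 and 0.28 after cyclic loess. With an estimated correlation the 5 lists had adjusted p = 0.61, 0.27, 0.56, 0.68 and 0.68, and DNA replication had 0.092 without mutant 25 °C replicate 2.

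The adult responses of the 2 genotypes overlapped heavily. In both genotypes 2776 genes rose and 1946 fell, where independent lists would share 515 and 429, and 12 genes were called in opposite directions. With each array centred on its median, 2471 rose and 2805 fell in both, so the balance of rises and falls depended on the scaling. Across genes, which are not independent replicates, the changes correlated at r = 0.857 (rho = 0.747).

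**Figure D2:**
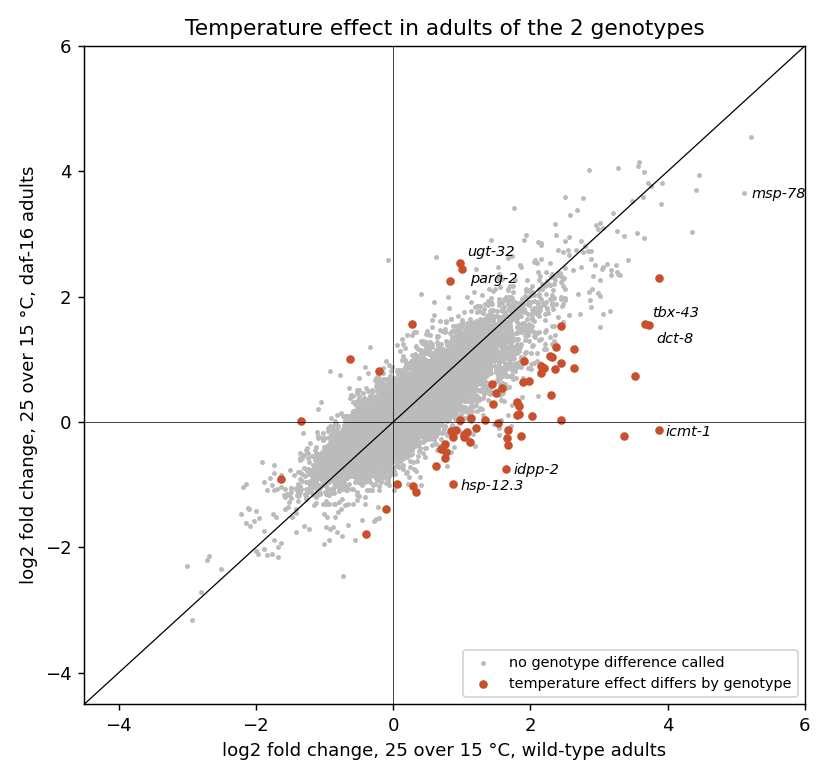
Change with temperature (25 °C over 15 °C, log2) of each gene in wild-type adults (horizontal) and daf-16 adults (vertical), with the 68 genes whose responses differed by the interaction test in red. Most points follow the diagonal (r = 0.857 across genes), and icmt-1, at 3.87 and -0.13, lies farthest below it among the named genes.

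A test of the difference itself found 68 genes whose temperature response in adults differed between the genotypes, 60 of them smaller or lower in the mutant. icmt-1 rose by 3.87 in the wild type and was at -0.13 in the mutant, a difference of -4 ± 0.38 (SE; limma adjusted p = 4.3e-06). idpp-2 rose by 1.65 in the wild type and fell in the mutant (-0.74), a difference of -2.39 ± 0.23 (adjusted p = 4.3e-06). dct-8 and tbx-43 rose in both, by 3.73 and 3.67 against 1.55 and 1.56, with differences of -2.19 (adjusted p = 0.0014) and -2.12 (adjusted p = 0.003). The small heat shock gene hsp-12.3 rose in the wild type (0.88) and fell in the mutant (-0.99), a difference of -1.87 (adjusted p = 0.033). Above 0 were parg-2 (1.44, adjusted p = 0.01) and ugt-32 (1.56, adjusted p = 0.025), which rose more in the mutant. Of the 60 genes, 28 rose in the wild type and were not called in the mutant, and 22 rose in both. The class 1 list lay below 0 as a whole, with a median of -0.38, 0 members called above and 2 below of 30 (adjusted over the list alone, 1 and 9), at camera adjusted p = 1.8e-08 and 2e-04 with an estimated correlation. The muscle, neuropeptide, sperm and early embryo lists lay below 0 (adjusted p = 0.00012, 8.7e-05, 8.7e-05 and 8.7e-05) and the class 2 and intestine lists above it (adjusted p = 0.0024 for both), with adjusted p = 0.42, 0.54, 0.33, 0.33, 0.078 and 0.6 with an estimated correlation. mtl-1 differed by 0.10 ± 0.44 (adjusted p = 1) and sod-3 by -0.32 ± 0.23 (adjusted p = 0.94). The sperm list had adjusted p = 0.067 without wild-type 25 °C replicate 2 and the intestine list adjusted p = 0.14 without wild-type 25 °C replicate 1. The gene count depended on single arrays. It was 44 and 37 without wild-type 15 °C replicate 1 or 3, 114 and 33 without wild-type 25 °C replicate 1 or 2, 37 and 41 without mutant 15 °C replicate 2 or 3, and 38 and 37 without mutant 25 °C replicate 1 or 3. It was 25 with only the adult arrays in the fit and 175 with array weights. With only the adult arrays, dct-8 (adjusted p = 0.055), tbx-43 (0.069), hsp-12.3 (0.085), parg-2 (0.056) and ugt-32 (0.073) lost their calls. ugt-32 lost its call in 8 of 12 runs without 1 array. These were wild-type 15 °C replicates 1 (adjusted p = 0.061) and 3 (0.069), wild-type 25 °C replicate 2 (0.076), mutant 15 °C replicates 2 (0.08) and 3 (0.086) and mutant 25 °C replicates 1 (0.056), 2 (0.055) and 3 (0.078). hsp-12.3 also lost its call in 8. These were wild-type 15 °C replicates 1 (adjusted p = 0.11) and 2 (0.091), wild-type 25 °C replicate 1 (0.062), mutant 15 °C replicates 1 (0.065), 2 (0.087) and 3 (0.091) and mutant 25 °C replicates 1 (0.11) and 3 (0.084). Its rise in the wild type had adjusted p = 0.078, 0.069 and 0.13 without wild-type 15 °C replicate 1, 15 °C replicate 2 or 25 °C replicate 1, and 0.069 with only the arrays compared.

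In wild-type larvae fewer genes were called than in adults, and mtl-1, fat-7 and spp-9 were among the 10 largest changes in their direction at both stages. irg-5, an infection response gene, rose by 4.78 ± 0.27 (SE), followed by sysm-1 (3.52), pud-4 (3.42), gtnt-17 (3.07), pud-3 (2.89), the lipase lipl-2 (2.86), gtnt-18 (2.81), cyp-37B1 (2.57), mtl-1 (2.32) and math-37 (2.29). The aspartyl protease asp-12 fell most, at -5.16 ± 0.19, followed by nspb-4 (-3.01), msrp-4 (-2.88), fat-7 (-2.74), zig-3 (-2.53), spp-9 (-2.40), fipr-2 (-2.34), cyp-33C8 (-2.24), pqn-31 (-2.17) and fipr-1 (-2.12). By limma 572 genes rose and 516 fell, 166 and 100 at least 2-fold, with adjusted p between 4.6e-14 and 0.0045 for those named. More fell than rose with each array centred on its median (592 and 515) and with array weights (643 and 522). DNA replication and cell cycle genes fell in 6 of 39 cases and rose in 0 (adjusted over the list alone, 17 and 0; adjusted p = 1.8e-09), with a median of -0.29. Oocyte and germ line genes fell in 8 of 36 and rose in 1 (adjusted over the list alone, 17 and 1; adjusted p = 4e-08), with a median of -0.33. With an estimated correlation these lists had adjusted p = 0.34 and 0.51. Heat shock protein genes fell in 3 of 21 cases and rose in 0 (adjusted over the list alone, 5 and 0; adjusted p = 0.007). Endoplasmic reticulum stress genes rose in 2 of 20, led by atf-6 (0.75), and fell in 0 (adjusted over the list alone, 5 and 0; adjusted p = 0.0024). Both lists had adjusted p = 0.48 with an estimated correlation. The heat shock call was lost without 15 °C replicate 2 (0.097) or 25 °C replicate 1 (0.07), and that of the stress genes without 15 °C replicate 1 (0.085). Moulting genes rose in 3 of 71 cases and fell in 4, grd-3 (-1.32) the most (the same over the list alone; adjusted p = 0.25). Collagens rose in 5 of 171 and fell in 6 (adjusted over the list alone, 6 and 8; adjusted p = 0.41). The gene count fell to 561 and 663 without 25 °C replicate 2 or 3, and to 368 with only these 6 arrays in the fit.

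In daf-16 larvae irg-5 (5.08 ± 0.27, SE), sysm-1 (3.78), pud-3 (3.06), pud-4 (2.84) and dod-24 (2.84) rose most and asp-12 (-3.82 ± 0.19), zig-3 (-2.96), msrp-4 (-2.87), fat-7 (-2.48) and nspb-4 (-2.37) fell most. Limma called 691 genes higher and 479 lower, 182 and 100 at least 2-fold, with adjusted p between 2.8e-11 and 3.6e-05 for those named. Oocyte and germ line genes fell in 7 of 36 cases and rose in 0 (adjusted over the list alone, 23 and 1; adjusted p = 1.3e-11). Detoxification genes rose in 23 of 184, led by cyp-37B1 (2.39), and fell in 6 (adjusted over the list alone, 30 and 7; adjusted p = 0.0021). Of 5 vitellogenins, the yolk proteins, 3 fell and 0 rose (adjusted over the list alone, 4 and 1; adjusted p = 0.0021), led by vit-5 (-1.89). With an estimated correlation these had adjusted p = 0.4, 0.42 and 0.42. The larval responses shared 321 genes that rose and 222 that fell in both genotypes, where independent lists would share 15.5 and 9.72, with 0 in opposite directions and r = 0.665 across genes (rho = 0.485). The count in the mutant was 662 without mutant larva 15 °C replicate 1, 602 without 25 °C replicate 3 and 541 with only these 6 arrays in the fit. Preparation 3 stood apart in both larval groups at 25 °C, at 19.7 in the wild type and 21.3 in the mutant on the second principal component of the larval arrays, where the other 4 lay between -15 and -3.94. The deviations of these 2 arrays from their group means correlated across genes at r = 0.45, and the cause is not known. Without them the mutant count was 684 and the wild-type count 798, from fewer arrays. Wild-type larva 15 °C replicate 1 lay farther out on the second component, at 29.5, where the others of its group were at 5.39 and -0.744. It was left out only in the runs without 1 array. The shared count was 359 without wild-type 25 °C replicate 2, 351 without preparation 3 of both 25 °C larval groups (chosen after seeing the data) and 199 with only the arrays compared. With array weights 334 rose and 335 fell in both.

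No gene was called in the test of whether the larval response differed between genotypes: limma gave 0 genes above and 0 below, with 1050 at an unadjusted p under 0.05, where 1272 of 25434 would be expected. mtl-1 rose in wild-type larvae by 2.32 (adjusted p = 5.7e-05) and was at 0.78 in the mutant (adjusted p = 0.18), but the difference of -1.54 ± 0.44 had adjusted p = 1. At 15 °C mtl-1 stood at 1.91 in wild-type larvae and 1.59 in mutant larvae, near the lower quartiles of those arrays (1.677 to 1.855). The size of its changes is therefore uncertain. Vitellogenins had a median difference of -0.48 with 0 members called (adjusted over the list alone, 0 above and 2 below; adjusted p = 9.5e-05), and adjusted p = 0.7 with an estimated correlation. Without mutant larva 25 °C replicate 3 the call had adjusted p = 0.073. The gene count was 2, 1 and 2 without wild-type larva 25 °C replicate 1, 2 or 3, and 1 with the preparation number as a block.

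**Figure D3:**
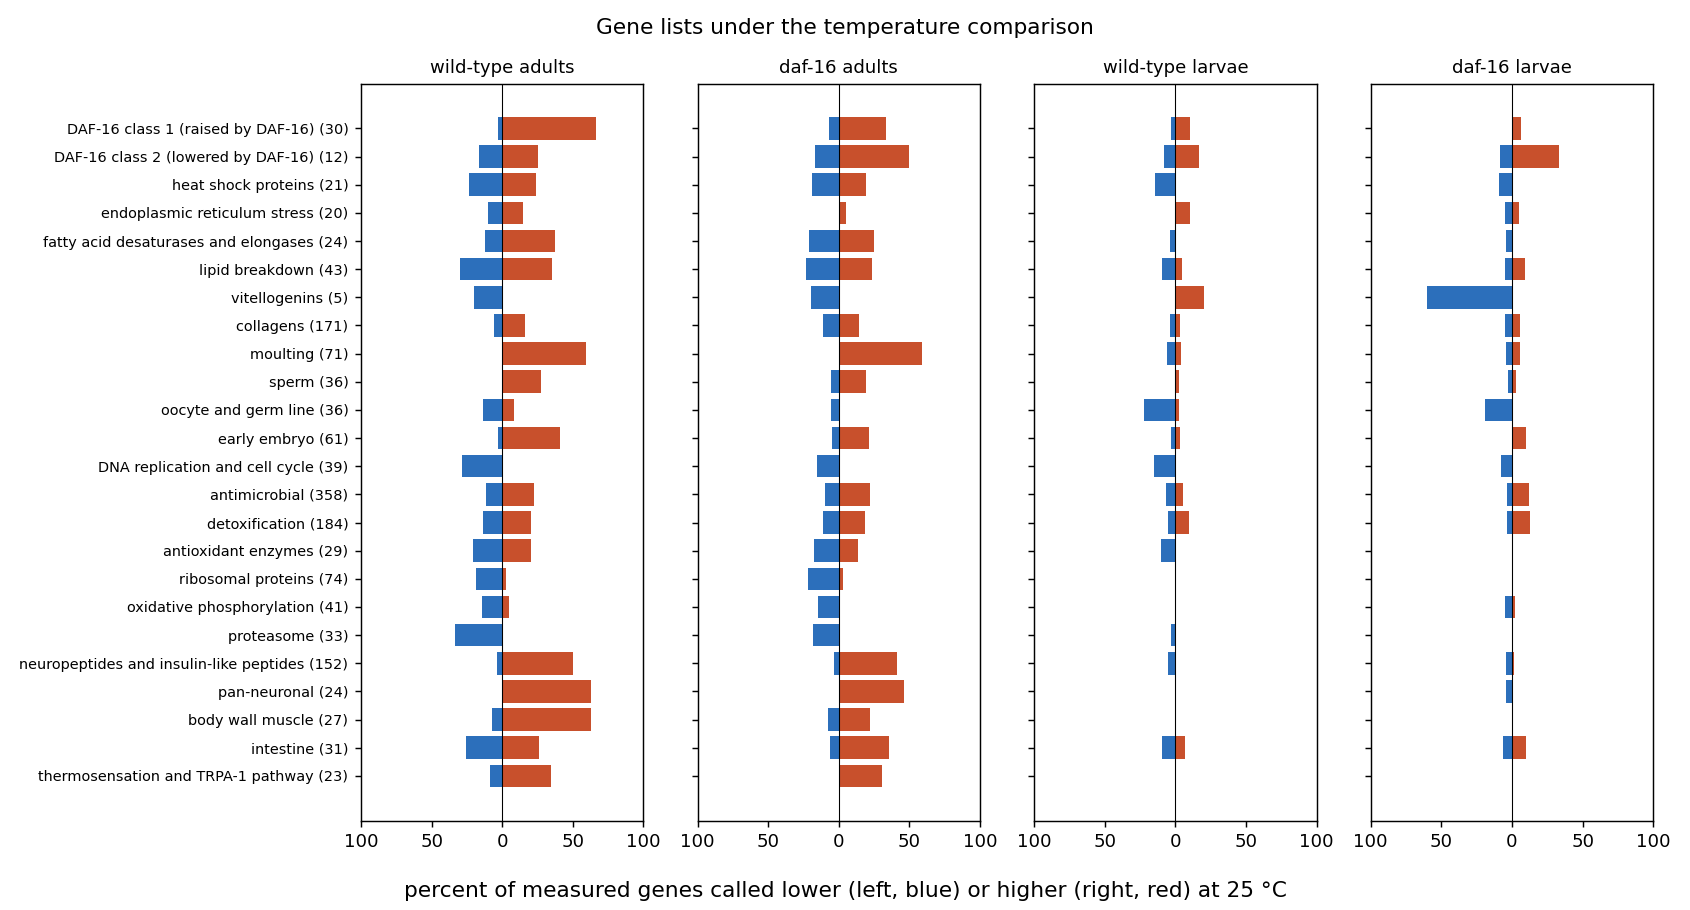
Percent of the measured genes of each of the 24 lists called lower (left) and higher (right) at 25 °C in the 4 temperature comparisons. In wild-type adults 42 of 71 moulting genes and 20 of 30 class 1 genes were called higher, against 3 and 3 in wild-type larvae; the falls of DNA replication, ribosomal and proteasome lists in wild-type adults lost their calls after cyclic loess.

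The response to temperature in the wild type differed between the stages for 3498 genes, 2202 with the adult change above the larval one and 1296 below it. Because adults were matched by days and larvae by stage, this difference also holds any difference in how far adult life had advanced. msp-78 (5.06 ± 0.86, SE), abf-2 (4.45), fipr-2 (4.01), icmt-1 (3.95) and dbd-13 (3.93) had the largest differences above 0, and abf-2 rose by 4.36 in adults and was at -0.08 in larvae. irg-5 (-3.26 ± 0.39), gtnt-17 (-3.07), gtnt-18 (-2.97), ugt-53 (-2.56) and pud-3 (-2.38) had the largest below 0, with irg-5 rising by 1.52 in adults and 4.78 in larvae. By limma adjusted p lay between 1.7e-08 and 0.014 for these genes. gtnt-18 had 0.051 without wild-type larva 25 °C replicate 2. Of the 3498 genes, 1901 rose in adults and were not called in larvae, and 61 rose in adults and fell in larvae. Lists above 0 with an estimated correlation too were class 1 (10 of 30 above and 1 below; adjusted over the list alone, 16 and 1; median 0.53), moulting (33 of 71 above and 1 below; adjusted over the list alone, 34 and 1; median 0.59) and neuropeptides (59 of 152 above and 1 below; adjusted over the list alone, 67 and 2; median 0.56). Their camera adjusted p was 1e-07, 1.4e-13 and 1.7e-18, and 5e-04, 0.045 and 0.045 with an estimated correlation. Class 1 members dod-6 (2.61), lys-7 (2.39) and far-3 (2.16) led the first, and nlp-49 (3.20) and ins-7 (2.81) the last. The pan-neuronal, muscle, sperm, early embryo and thermosensation lists also lay above 0 (adjusted p = 3.9e-05, 3.9e-05, 0.0011, 0.0027 and 0.0069), with adjusted p = 0.19, 0.28, 0.29, 0.29 and 0.25 with an estimated correlation. The ribosomal list lay below 0 (adjusted p = 0.0027), as did the proteasome (0.04) and oxidative phosphorylation (0.05) lists, and the desaturase and antimicrobial lists lay above it (both 0.05). With an estimated correlation these had adjusted p = 0.74, 0.74, 0.74, 0.29 and 0.42. After cyclic loess the 3 below 0 had adjusted p = 0.46, 0.86 and 0.63, and all but the ribosomal list lost their calls in several runs without 1 array. With the preparation number as a block, 10 lists were called for temperature by stage, against 13 in the fit reported. Both stages were tested as differences within a stage, but a compressed scale in 1 of the normalizations, which appear to be separate, would change the size of its differences. With each array centred on its median, the share above 0 moved from 63.0% to 52.8% of 3714 genes.

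Some genes responded alike at both stages: 265 rose in wild-type adults and larvae and 195 fell, where independent lists would share 86.6 and 77.4, among them mtl-1 and lipl-2 upward and fat-7 and spp-9 downward. Another 85 were called in opposite directions, where 164 would be expected, and the changes correlated at r = 0.273 (rho = 0.28) across genes. The shared count of 460 was 242 and 284 without wild-type larva 25 °C replicate 2 or 3, and 156 with only the arrays of each comparison in its fit. More fell than rose with each array centred on its median (264 and 227) and with array weights (269 and 255).

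Between the genotypes few genes were called in adults at 15 °C. By limma 3172 genes had an unadjusted p under 0.05, where 1272 would be expected, so more may differ than were called. lact-6, a beta-lactamase-like gene, was higher in the mutant by 2.39 ± 0.42 (SE; limma adjusted p = 0.003, but 0.12 with only these arrays in the fit), fbxb-40 by 2.3, arrd-1 by 1.51, snb-7 by 1.5 and the zinc finger gene ref-2 by 1.47. Besides daf-16 itself, cls-3 (-1.94 ± 0.32), ent-6 (-1.83), a nucleoside transporter, fbxa-162 (-1.65) and the insulin-like gene ins-23 (-1.46) were lowest among genes with a name of letters and a number. The test called 244 genes higher and 130 lower in the mutant, 74 and 40 at least 2-fold, with adjusted p at most 0.016 for those named. fbxa-162 had 0.065, 0.075 and 0.081 without wild-type replicate 2, mutant replicate 1 or mutant replicate 3, and with only these arrays fbxa-162 had 0.22 and snb-7 had 0.14. Early embryo genes were higher in 10 of 61 cases and lower in 0 (adjusted over the list alone, 17 and 0), such as sdz-25 (1.39) and tbx-37 (1.32; 0.056 without wild-type replicate 3 and 0.058 with only these arrays), at camera adjusted p = 8.5e-13 and 0.019 with an estimated correlation. Class 1 genes were higher in 0 of 30 cases and lower in 1, lys-7 at -1.09 (adjusted over the list alone, 1 and 4), at adjusted p = 0.00015 and 0.011 with an estimated correlation. lys-7 itself lost its call without wild-type replicate 2 (0.13) or mutant replicate 1 (0.071) or 3 (0.11), and with only these arrays (0.15). Ribosomal protein genes were lower in 3 of 74 cases and higher in 0 (adjusted over the list alone, 12 and 0; adjusted p = 4.2e-14, adjusted p = 0.56 with an estimated correlation), with a median of -0.19. The gene count was 168, 158 and 156 without wild-type replicate 3, mutant replicate 2 or mutant replicate 3, 70 with only these arrays in the fit and 797 with array weights.

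At 25 °C more adult genes were called between the genotypes than at 15 °C. icmt-1 (-3.87 ± 0.27, SE), ins-23 (-2.78), dct-8 (-2.58), dlhd-1 and the sugar transporter swt-3 (-2.19) were lower in the mutant, and irg-4, an infection response gene (2.94 ± 0.42), fipr-1 (2.12), parg-2 (2), lact-6 (1.96) and sdz-6 were higher. Limma called 345 genes higher and 417 lower, 65 and 138 at least 2-fold, with adjusted p at most 0.009 for those named. With each array centred on its median 446 were higher and 368 lower, so the share that was higher moved from 45.3% to 54.8%. lact-6 had 0.08 and 0.057 without wild-type replicate 2 or mutant replicate 1. Of 30 class 1 genes, 14 were lower and 1 higher (adjusted over the list alone, 21 and 2), with a median of -0.67. They included the cytochrome P450 gene cyp-34A9 (-1.54, adjusted p = 0.0062, or 0.057 without wild-type replicate 2), lys-7 (-1.5), hsp-12.3 (-1.48) and the lysosomal lipase lipl-4 (-1.37). The list had camera adjusted p = 1.9e-20 and 6.3e-07 with an estimated correlation, while sod-3 was at -0.45 (adjusted p = 0.17) and mtl-1 at -0.48 ± 0.31 (adjusted p = 0.57). The means of sod-3, 3.46 in the wild type and 3 in the mutant, lay below the adult array medians. Lipid breakdown genes were lower in 4 of 43 cases and higher in 0 (adjusted over the list alone, 6 and 1; adjusted p = 7e-04), led by lipl-2 (-1.49). Ribosomal protein genes were lower in 6 of 74 and higher in 0 (adjusted over the list alone, 19 and 0; adjusted p = 1.3e-13). Both lists had adjusted p = 0.47 with an estimated correlation. The gene count was 386, 464 and 395 without wild-type replicate 2, mutant replicate 2 or mutant replicate 3, 390 with only these arrays in the fit and 2059 with array weights.

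In larvae few single genes were called between the genotypes. At 15 °C, 5 genes were higher and 13 lower in the mutant. Among genes with a name of letters and a number, clh-2 (0.97 ± 0.19, SE), gly-1 (0.94) and nstp-7 (0.92) were the highest and daf-16, sdz-24 (-2.1 ± 0.27), ent-6 (-1.81) and the phosphatase gene scpl-1 (-1.24) the lowest. By limma adjusted p was 0.042, 0.026 and 0.018 for the higher genes and at most 0.00074 for the lower ones. clh-2 lost its call without wild-type replicate 1 (adjusted p = 0.16) or 2 (0.057) or mutant replicate 1 (0.13) or 3 (0.15). nstp-7 lost it without wild-type replicate 2 (adjusted p = 0.11) or 3 (0.076) or mutant replicate 1 (0.13) or 2 (0.08). gly-1 lost it without each of the 6 arrays, at adjusted p = 0.061, 0.08 and 0.086 without wild-type replicates 1, 2 and 3 and 0.08, 0.11 and 0.094 without mutant replicates 1, 2 and 3. With only these arrays in the fit 5 genes were called, and clh-2 (0.62), gly-1 (0.076), nstp-7 (0.44) and scpl-1 (0.098) lost their calls. At 25 °C, 3 were higher, delm-2 (1.12 ± 0.17) the most, and 27 lower. Among those with a name of letters and a number, ent-6 (-1.89), mtl-1 (-1.87 ± 0.31), the long noncoding RNA tts-1 (-1.48) and the nicotinamide nucleotide transhydrogenase gene nnt-1 (-1.39) were the lowest after daf-16. The genes named had adjusted p = 0.0058 at most, but delm-2 (0.17) and mtl-1 (0.32) lost their calls with only these arrays in the fit. mtl-1 had 0.066, 0.056 and 0.077 without wild-type replicate 3, mutant replicate 1 or mutant replicate 2. Class 1 genes were lower as a list at both temperatures, with medians of -0.25 and -0.29. Of 30, 1 and 4 were lower and 0 higher (adjusted over the list alone, 8 lower and 0 higher at 15 °C and 10 and 1 at 25 °C), at camera adjusted p = 1.9e-07 and 6.4e-11, and 0.00054 and 4.3e-05 with an estimated correlation. Class 2 genes were higher as a list, with medians of 0.16 and 0.31 and 0 of 12 called (adjusted over the list alone, 2 and 4 higher and 0 lower), at adjusted p = 0.0012 and 1.9e-05, and 0.047 and 0.0061 with an estimated correlation. Of these 12, 2 are vitellogenins, a list with a median of 0.7 at 15 °C (camera adjusted p = 1.9e-07, and 0.11 with an estimated correlation). Desaturase and elongase genes were higher at 25 °C with a median of 0.13 and 0 of 24 called (0 adjusted over the list alone; adjusted p = 2.5e-05, adjusted p = 0.022 with an estimated correlation).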

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

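The tests of larvae among the adults and of the germ line share were chosen only after the results they address had been seen; the test of males, that of array scaling and the shuffled labels were chosen before.

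The effect of temperature in adults differed between the genotypes by a test of the difference itself for 68 genes, among them icmt-1 (-4), idpp-2 (-2.39), dct-8 (-2.19), tbx-43 (-2.12), hsp-12.3 (-1.87), parg-2 (1.44) and ugt-32 (1.56). The class 1 list had a median difference of -0.38. Genotype labels were then shuffled within each temperature, after centring each genotype. Of 100 draws of the labels, the real one included, 1 gave as many genes, and the highest other gave 14. Chance is thus unlikely if the preparations are independent, which the labels do not say. The same test in larvae called 0 genes, so all 100 draws had to give as many and say nothing about chance there. The highest other gave 6. The effect in the wild type differed between the stages for 3498 genes. With stage labels shuffled in the same way, 1 of 100 draws, the real one, gave as many and the highest other gave 580. Chance is unlikely there too, under the same condition. The named genes were msp-78 (5.06), abf-2 (4.45), fipr-2 (4.01), icmt-1 (3.95), dbd-13 (3.93), irg-5 (-3.26), gtnt-17 (-3.07), gtnt-18 (-2.97), ugt-53 (-2.56) and pud-3 (-2.38), and the lists class 1 (0.53), moulting (0.59) and neuropeptides (0.56).

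Probe sets without a single gene name also carried signal. Of 3833 such probe sets, limma called 519 for temperature in wild-type adults, 327 in daf-16 adults, 60 in wild-type larvae and 114 in daf-16 larvae. Each was a smaller share than among the 25434 genes, of which 30.1%, 24.6%, 4.28% and 4.6% were called. For genotype limma called 6 in adults at 15 °C, 103 in adults at 25 °C, 0 in larvae at 15 °C and 7 in larvae at 25 °C. It called 10 for temperature by genotype in adults and 145 for temperature by stage. Of 30 probe sets shared by several major sperm protein genes, 21 were higher at 25 °C in wild-type adults (median 2.66) and 17 in daf-16 adults (median 1.8). Their median level went from 3.62 to 5.98 in wild-type adults and from 3.89 to 5.35 in daf-16 adults, and lay between 8.13 and 8.31 in larvae.

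Of 36 sperm genes, 10 were higher at 25 °C in wild-type adults (camera adjusted p = 0.00027, but 0.26 with an estimated correlation), and 7 were higher and 2 lower in daf-16 adults (camera adjusted p = 0.11), and males or larvae among the adults might bring the rises. Genes at least 2 log2 units higher in wild-type larvae than in wild-type adults at 15 °C are termed larva-high. Larvae like the late L4 samples, as the whole cause, are argued against only weakly. Larva-high sperm genes imply a median share of larval RNA of 7.1% (95% bootstrap bounds 0.82 and 9.6). The 73 larva-high collagens imply 0.02% (-0.081 and 0.5), though 14 of them were called higher and 3 lower. These shares set levels from apparently separate normalizations side by side. The bootstrap resampled genes as if independent and holds no spread between preparations, so the small gap between 0.5 and 0.82 decides little. The first test of larvae, run before that of the implied shares, left larvae open, with 46.7% of 15 larva-high sperm genes called higher (exact 95% bounds 21.3 and 73.4). Males stay open too, since of 14 male soma genes 2 were called higher and 1 lower, with a median change of -0.12 (95% bootstrap bounds -0.23 and 0.064), and 1 was above log2 5 in wild-type adults at 25 °C. A smaller contribution of late L4 larvae, larvae of other stages, embryos and a change in the sperm that hermaphrodites keep also stay open and were not tested. How far adult life had advanced at each temperature was not tested either.

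In wild-type adults 15 of 24 neuron, 17 of 27 muscle and 42 of 71 moulting genes were higher at 25 °C (adjusted p = 0.085, 0.24 and 0.042 with an estimated correlation), and in daf-16 adults 11, 6 and 42 (0.11, 0.61 and 0.054), which could come from array scaling, larvae or a smaller germ line. Of 74 genes called higher among 122, 67 stayed so with each array centred on its median and 74 after cyclic loess, which argues against scaling differences left after RMA. Both settings start from the values that RMA had already normalized, so a distortion made in that step stays open. The first test of larvae went with them as a source, with 57% of the 200 genes most in excess in larvae called higher (exact 95% bounds 49.8 and 64). Of all 25434 genes, 3851 were called higher. The 200 were ranked against wild-type adults at 15 °C, which are also the baseline of the change, and the bounds treat genes as independent. Of these 200, 49 were collagens and 6 were sperm genes. Among moulting genes, 18 of 30 larva-high ones and 24 of 41 others were called higher (medians 0.86 and 0.56). The rise was thus not limited to genes past the larva-high cutoff. The others can still stand higher in larvae, so their rise does not weigh against larvae as a source. The collagen comparison, chosen after the first result was seen, argues against larvae like the late L4 samples as the whole cause. The implied share of larval RNA was 8.5% for 37 genes of the 3 lists (95% bootstrap bounds 3.9 and 21), against 0.02% for the collagens. Of these 73 collagens, 14 were called higher and 3 lower. The bootstrap bounds in this paragraph also resample genes as if independent and hold no spread between preparations. Of the 37, the 30 moulting genes implied 5.5% (3.3 and 14) and the 7 neuron and muscle genes 30% (14 and 35). The germ line share cannot be told apart from other causes, because pan-neuronal genes exceeded intestine genes by 0.48 (95% bootstrap bounds -0.04 and 0.9), an interval that includes 0. The oocyte and germ line list itself had a median of -0.14, little below the -0.098 of all genes, with 3 of 36 genes called higher and 5 lower. A partial contribution of larvae, other stages, how far adult life had advanced and a biological response of these tissues to temperature stay open, as untested.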

How the results depend on the processing

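The alternative without preparation 3 of both larval groups at 25 °C was chosen after seeing the data, because these 2 arrays stood apart from the other larval arrays at 25 °C, and all others before. Wild-type larva 15 °C replicate 1, farther out on the second principal component (29.5 against 19.7 and 21.3), was kept in that alternative. Counts of genes and lists stayed within 1.5 times the reported count under cyclic loess, median centring, an intensity trend with robust shrinkage, averaged probe sets and without the dimmest genes, for all 25 counts each. The balance of rises and falls did turn with median centring for temperature in both adult genotypes and in wild-type larvae, for genotype in adults at 25 °C and for calls shared by the stages and by the adult genotypes. For some of the temperature counts it also turned with the block, the intensity trend, array weights or without preparation 3. With the preparation number as a block, 28 genes were called for genotype in larvae at 15 °C and 1 for temperature by genotype in larvae. With only the arrays compared, the counts were 368 for temperature in wild-type larvae, 541 (6 lists) in daf-16 larvae, 70 and 390 for genotype in adults at 15 and 25 °C, 5 in larvae at 15 °C, 25 for temperature by genotype in adults, and 156 and 199 for calls shared by the stages and by the larval genotypes, where fewer arrays estimate the spread. With array weights they were 797 and 2059 for genotype in adults at 15 and 25 °C, 28 in larvae at 15 °C, 175 for temperature by genotype in adults, and 3 lists for it in larvae. The cause was not tested for the block and the weights. With at least a 2-fold change, fewer genes passed by construction: 1795 and 1418 for temperature in wild-type and daf-16 adults, 266 and 282 in larvae, 114, 203, 10 and 18 for genotype in adults and larvae at 15 and 25 °C, 1675 for temperature by stage, and 68, 1080 and 159 for calls shared by the stages, the adult genotypes and the larval genotypes. With an estimated correlation the lists called were 2 and 0 for temperature in wild-type and daf-16 adults, 0 and 0 in larvae, 2, 1, 2 and 3 for genotype in adults and larvae at 15 and 25 °C, 1 and 0 for temperature by genotype in adults and larvae, and 3 for temperature by stage. Without preparation 3 of both larval groups at 25 °C, 684 genes were called for temperature in daf-16 larvae, 351 were shared by the larval genotypes and 3 lists were called for temperature by genotype in larvae; fewer arrays were compared.

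Leaving out each array in turn gave, for temperature, 6165 to 6988 genes and 11 to 13 lists in wild-type adults, 4220 to 5585 and 9 to 12 in daf-16 adults, 561 to 1103 and 3 to 7 in wild-type larvae, and 602 to 1123 and 8 to 12 in daf-16 larvae. For genotype it gave 156 to 326 and 6 to 13 in adults at 15 °C, 386 to 954 and 7 to 8 in adults at 25 °C, 14 to 21 and 7 to 13 in larvae at 15 °C, and 24 to 32 and 8 to 14 in larvae at 25 °C. For temperature by genotype it gave 33 to 114 and 6 to 10 in adults and 0 to 2 and 0 to 12 in larvae, and for temperature by stage 2906 to 3292 and 9 to 13. Shared calls ranged from 242 to 461 for the stages, 3364 to 4528 for adults and 359 to 578 for larvae. The lists for temperature by genotype in larvae numbered 3, 12, 12 and 0 without wild-type larva 25 °C replicates 2 and 3 and daf-16 larva 25 °C replicates 2 and 3, against 6 reported. Those for genotype in adults at 15 °C numbered 7 and 6 without daf-16 replicates 2 and 3, against 11. Lists for temperature in wild-type larvae numbered 3 without 15 °C replicate 2 or 25 °C replicate 1. Those for genotype in larvae at 15 °C numbered 7 without daf-16 replicate 3.

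Of 604 values of named genes, the call was lost for 132 with only the arrays compared, 24 with the block, 20 after cyclic loess, 10 with array weights, 9 with median centring, 3 with the intensity trend and 40 without preparation 3, which bears only on comparisons with those larvae. Of 264 values of lists it was lost for 92 with an estimated correlation, 16 after cyclic loess, 16 with array weights, 11 without the dimmest genes, 10 without preparation 3, 8 with only the arrays compared, 6 with the block and 2 with median centring, and gained for 10 after cyclic loess and 11 without the dimmest genes. Both totals include values not called in the fit reported, which could not lose a call, so the losses are not shares of these totals. With an estimated correlation most of the list calls were lost. In runs without 1 array, calls were lost 573 times for named genes and 120 times for lists, and gained 1 and 71 times, a gene or list counting once per run. The planned comparison of stages was not run, because the stages appear to have been normalized separately. Signal near background limits dim genes, and near-identical genes such as msp, nspd, col and fbxb are hard to tell apart.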

Other observations

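The test on the chromosome of daf-16 was chosen before its result was seen, and that on class 1 genes among the recurrent genes after.

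The 6 arrays of a comparison of 2 groups split in 10 ways, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes as observed. The other splits mix the 2 groups, so a real difference enters their spread and lowers their counts. Their counts are thus no measure of what chance gives. For temperature the real split and the highest other gave 7667 and 6 genes in wild-type adults, 6258 and 0 in daf-16 adults, 1088 and 9 in wild-type larvae, and 1170 and 0 in daf-16 larvae. For genotype they gave 374 and 4 in adults at 15 °C, 762 and 5 in adults at 25 °C, 18 and 2 in larvae at 15 °C, and 30 and 1 in larvae at 25 °C.

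Besides daf-16, 2 genes were lower in the mutant in all 4 genotype comparisons: ent-6 (-1.83, -1.84, -1.81 and -1.89) and Y54G2A.36 (-1.28, -2.37, -1.43 and -2.63), the latter chosen after its values were seen. With daf-16, 59 genes were lower in at least 2 comparisons and 9 in at least 3, and 48 and 0 were higher. Sequence differences linked to the deletion might produce such genes, but a share of 0.121 of the 58 other genes lay on chromosome I with daf-16 (7 genes, exact 95% bounds 0.0499 and 0.233), against 0.128 of the genes tested (one-sided hypergeometric p = 0.63, an exact test), which argues against linkage as the source of most of them. Among the 58, 2 belonged to class 1, where 0.068 would be expected (one-sided hypergeometric p = 0.0021, an exact test). Linkage for single genes and direct regulation by DAF-16 stay open.

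Levels of the lists in wild-type adults and larvae were not tested, because the stages appear to have been normalized separately. The median gene stood 0.769 log2 units higher in adults than in larvae. The median difference was 3.16 for vitellogenins, 2.22 for DNA replication genes and 1.84 for oocyte genes, and -1.31 for sperm genes, -1.05 for collagens, -0.782 for muscle genes and -0.696 for moulting genes.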
